A study of Mus musculus with 6 samples.

How the data were processed

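RNA was measured in cortical cells from mouse embryos of dams given saline or phenobarbital, a barbiturate that enhances GABA-A receptor currents. Per the labels' protocols, C57BL/6N dams received 80 mg/kg from a stock of 8 mg/mL, in paired injections 6 h apart, on embryonic days 10 to 11. Cortex was taken at embryonic day 12 in the protocol and 12.5 in the sample labels. The cells were dissociated and plated, and their RNA was isolated 4 h after plating. Per the labels' protocols, 0.2 µg of RNA was labelled with Cy3 and hybridised to 1-colour Agilent arrays. Each group holds 3 arrays. The labels do not say whether the replicates came from separate litters or cultures, so p-values measure only the spread between these samples, which may be technical.

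Per the file headers, the authors scanned the arrays and quantified them with Agilent Feature Extraction 10.7.3.1 (10.7 in the submitters' processing notes). The header's array annotation uses genome build mm9. The deposited spot values are intensity on a linear scale, background-subtracted and detrended within each array, with no scaling between arrays. The authors' value table holds log2 values, per the comparison with the scanner files. Its differences between arrays equalled those of the log2 processed signals with 1 factor per array removed, to within 2.52e-06 for 99% of probes. Each probe in that table is centred on a constant that stays unknown, while its scale and direction were settled by this comparison. Its column medians were 0.08, 0.10 and 0.09 in control replicates 1 to 3 and -0.02, -0.09 and -0.08 in phenobarbital replicates 1 to 3.

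Each array held 62976 spots, of which 59305 were not controls. The main values were log2 of the processed signal minus each array's 75th percentile over these spots. Spots called non-uniform or population outliers by the software were set to missing, 98 to 198 per array. No spot outside the controls was saturated. Replicate spots of a probe were averaged. Of 55681 probes, 26582 carried an accession held in the RefSeq gene table given with the series (GRCm38.p6), which was used for names only, and these stood for 20145 genes. The other 29099 probes kept the file's name. A probe was kept if it was well above background on every array of at least 1 group and had at least 2 values per group, which left 34673 probes. Where several probes of a gene passed, the one with the highest mean signal was tested, giving 25304 names, 15181 of them gene symbols.

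Groups were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with no covariates. The tests were two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. Log2 fold changes are phenobarbital minus control, with the standard error (SE) of the fit. A gene below background on every array of a group has a bound. The bound sets the brighter group's mean against the dimmer group's mean of, per array, the higher of the gene's own signal and the lowest signal among probes well above background.

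Gene lists were compared with all other genes by camera with a preset correlation of 0.01, over the 28 lists with at least 3 tested members. The same lists were tested with an estimated correlation and with fry, which asks whether a list's genes move one way on balance. The lists, the rule for naming genes and the other settings listed next were chosen before the data were examined. Named were the 12 genes with the largest absolute log2 fold change in each direction, among those past the threshold with groups that did not overlap and a gene symbol. Also named were up to 4 members of each list past the threshold, by smallest p, or the 2 brightest members where none passed. Slc6a6, Slc12a2, Slc12a5 and the GABA-A subunits above background were named in any case, and further members only where they fix a list's count. Some genes selected by these rules are not given in the text.

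These settings changed the background correction, the scaling, the filter on dim probes, the treatment of outlier spots, the choice of probes, the variance prior, the array weights and the source of the values. They also added the replicate number or the slide as a block and left out each replicate in turn. The normexp correction was planned on mean spot signals and was run on median spot signals, because the files hold no column of means. Chosen after the data were seen were the slide as a random block, the mean over a gene's probes, and a restriction to genes whose probes lay within 1 of each other on the log2 scale. So were 3 lists, of further choroid plexus genes, motile cilia genes, and diencephalon and eye genes.

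The fit was tested on simulated data for this comparison, with the spreads of all 25304 genes and 200 genes changed by known amounts. It recovered 64 of 100 genes changed by 1 on the log2 scale and 97 of 100 changed by 2, with 15 false calls. The number of arrays limits the precision.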

Results

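The series asks how GABA-A receptors and taurine from the mother bear on neural progenitor cells of the developing mouse cortex. The arrays address 1 part of it, whether phenobarbital given to the dam changes RNA levels in the embryos' cortical cells. The comparison holds 3 arrays from control and 3 from phenobarbital-exposed embryos. Between 62.8% and 68.7% of the spots were well above background. The 75th percentile of the signal was 1116 to 1291 on the control arrays and 1803 to 1862 on the phenobarbital arrays (exact permutation test, two-sided p = 0.1, the smallest that 3 arrays against 3 allow). Control replicate 1 and all 3 phenobarbital arrays were on slide 1, control replicate 2 on slide 2 and control replicate 3 on slide 3, and the scan dates split the arrays in the same way. No pair of arrays was a duplicate: at most 1 of the spot signals was equal between any 2 arrays. Pearson's r across tested genes, which are not independent replicates, ran from 0.993 to 0.996 between phenobarbital arrays. It was 0.996 between control replicates 1 and 3, and 0.988 and 0.983 between control replicate 2 and these. Between a control and a phenobarbital array it was 0.976 to 0.988. Control replicates 1 and 3 thus lay at least as near to phenobarbital replicate 1 as to control replicate 2.

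Of 8 tested genes of the choroid plexus, the epithelium that forms at the midline and makes cerebrospinal fluid, 5 rose with phenobarbital. Among them was Ttr, which had the highest log2 fold change of the named genes. The choroid plexus list passed the camera test upward, and the lists of erythroid cells and of mural cells and meninges passed it downward (adjusted p = 0.000147, 0.00766 and 0.0278). None of these lists passed with an estimated correlation (adjusted p = 0.432, 0.775 and 0.687). Across 25304 names, 4234 changed (limma, adjusted p below 0.05), of which 1580 rose and 2654 fell, and 1158 changed at least 2-fold. At an unadjusted p below 0.05 there were 9030. The groups did not overlap for 44.1% of genes, where chance gives 10%. The median log2 fold change of all genes tested was -0.16, and the shifts of the lists that passed are given relative to it, beside their medians as measured. The share of rises among the calls was 37.3%. It was 53.5% after quantile normalization (1596 rose, 1385 fell), 58.4% after scaling to the median (1442 rose, 1028 fell), 59.4% with the percentile taken over probes above background on all arrays (1612 rose, 1104 fell), and 24.4% with normexp (1525 rose, 4735 fell). With the slide as a block, which sets control replicate 1 against the 3 phenobarbital arrays within slide 1, 771 genes changed (608 rose, 163 fell). With the slide as a random block, 3137 changed. All 4233 main calls that could be fitted with the slide block kept their sign. This was fixed in advance for genes whose groups did not overlap, since control replicate 1 also entered the calls. Without control replicate 1, 889 genes changed, and without phenobarbital replicate 2, 881. Without control replicate 3 the count was 1795, and without phenobarbital replicates 1 and 3 it was 1109 and 1260. Control replicate 2, the array farthest from the rest, could be left out with 4406 genes changed.

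In the choroid plexus list 5 genes rose, none fell and 3 did not pass, and the counts adjusted over the list alone were the same. Ttr, the thyroid hormone carrier secreted by this epithelium, rose by 4.95 ± 1.04 (SE, n = 3 per group) on the log2 scale, 31.0-fold with a 95% interval of 5.52 to 174 (limma, adjusted p = 0.0292). Its control values spread widely (-1.69 ± 2.17, SD) against those with phenobarbital (3.26 ± 0.67). The transcription factor Otx2 rose by 1.98 ± 0.39 (adjusted p = 0.0251), the folate receptor Folr1 by 1.84 ± 0.24 (0.00838) and the chloride channel Clic6 by 1.77 ± 0.30 (0.0185). A second Folr1 probe rose by 1.11. Kcne2, a potassium channel subunit, was not well above background on any control array and was at least 2.91-fold higher (adjusted p = 0.0312), though with normexp, whose offset shrinks the changes of dim genes, its log2 fold change was 0.67 and did not pass. The list's median lay 1.97 above that of all genes. As measured it was 1.80, or 1.65 with Kcne2 at its bound. The camera test gave an adjusted p of 0.000147, and an adjusted p of 0.432 with an estimated correlation. With the slide as a block, which rests on control replicate 1 alone and leaves out the spread between controls, the list's median as measured was 2.23.

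Genes outside the choroid plexus list with the largest rises included Sostdc1, a BMP and Wnt antagonist. Whether these genes came from the same epithelium was not tested. Sostdc1 rose by 3.35 ± 0.55 (limma, adjusted p = 0.0167), and 2.94 on its other probe. The non-coding Six3os1 rose by 3.32 ± 0.77 and the phosphatidate phosphatase gene Lpin1 by 2.74 ± 0.21. Below background on every control array were Calml4, at least 4.43-fold higher, the cation channel gene Trpm3, at least 4.32-fold, and the glutathione transferase gene Gsta1, at least 4.16-fold. So were Meig1, at least 3.69-fold higher, the serotonin receptor gene Htr2c, at least 3.48-fold, and Smoc1, at least 2.96-fold. These bounds hold for the processed signals: with normexp the log2 fold changes were 1.077 for Calml4, 0.78 for Trpm3, 0.91 for Gsta1, 0.73 for Meig1, 0.69 for Htr2c and 0.58 for Smoc1, and Gsta1, Htr2c and Smoc1 did not pass. Tmem132d, measured above background on 1 of 3 control arrays, rose by 2.63 ± 0.39.

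**Figure D1:**
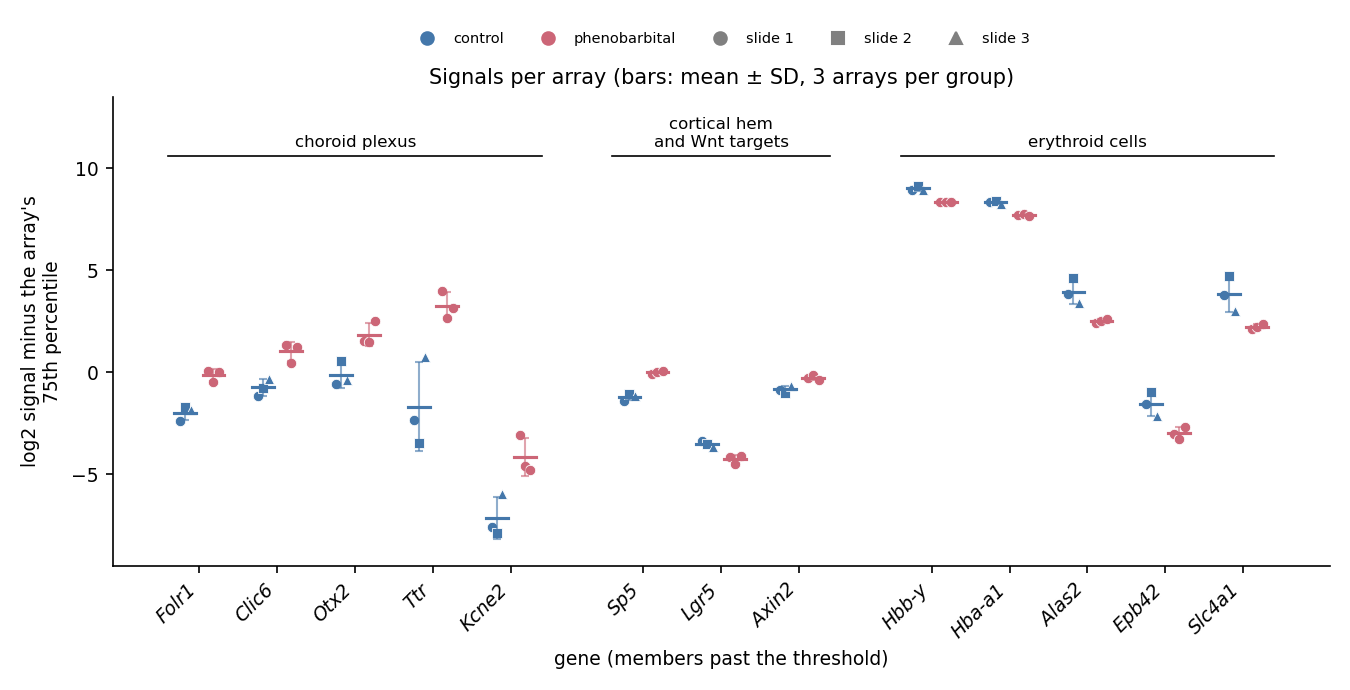
Log2 signal minus the array's 75th percentile (vertical axis) for members of 3 gene lists past the threshold; points are arrays, colour shows the group, shape the slide, and bars the mean ± SD of 3 arrays. Ttr sits at -1.69 ± 2.17 in controls and 3.26 ± 0.67 with phenobarbital, while Hbb-y and Hba-a1 differ by under 1 on the log2 scale, and Hbb-y changes sign after quantile normalization.

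The list of cortical hem genes and Wnt targets passed the camera test upward (adjusted p = 0.000147, and an adjusted p of 0.295 with an estimated correlation). The hem is the signalling centre of the medial cortex beside the choroid plexus. Of 14 members tested, 2 rose, 1 fell and 11 did not pass, and adjusted over the list alone 6 rose and 1 fell. The Wnt-induced factor Sp5 rose by 1.21 ± 0.12 (limma, adjusted p = 0.00437), and Axin2, a feedback inhibitor of Wnt signalling, by 0.57 ± 0.13 (0.0349), with 0.83 on its other probe. Lgr5, a receptor for R-spondins, fell by 0.73 ± 0.14 (0.0253). With every probe tested, dimmer probes of Wnt8b, Tcf7 and Nkd1 rose by 1.61, 1.59 and 1.03, while the brightest probes of these genes did not pass. In all, 12 of the 14 had a positive log2 fold change, and the list's median lay 0.72 above that of all genes. As measured it was 0.56, and with the slide as a block, which rests on control replicate 1 alone, it was 0.56 as well. Among 12 genes of Cajal-Retzius cells, early neurons partly born at the hem, Reln and Calb2 rose, by 1.28 ± 0.27 and 1.15 ± 0.28, and 10 did not pass. Reln was above background on 2 of 3 control arrays, and with normexp Reln and Calb2 had 0.28 and 0.29 and did not pass. Of 18 genes responding to Hedgehog or FGF, 4 rose and 14 did not pass: Fgf15 rose by 1.55 ± 0.32, Gli2 by 0.97 ± 0.10, Spry1 by 0.73 ± 0.15 and Etv4 by 0.72 ± 0.14, with 2.01 on its other probe. Adjusted over the list alone 5 rose. With every probe tested, a dimmer probe of Etv1 fell by 0.71, while its brightest probe did not pass. The Cajal-Retzius list and the Hedgehog and FGF list did not pass the camera test (adjusted p = 0.347 and 0.0665), though the latter passed in 5 of 21 alternatives (normexp, scaling to the median, no filter on dim probes, the mean of a gene's probes, and without phenobarbital replicate 1).

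**Figure D2:**
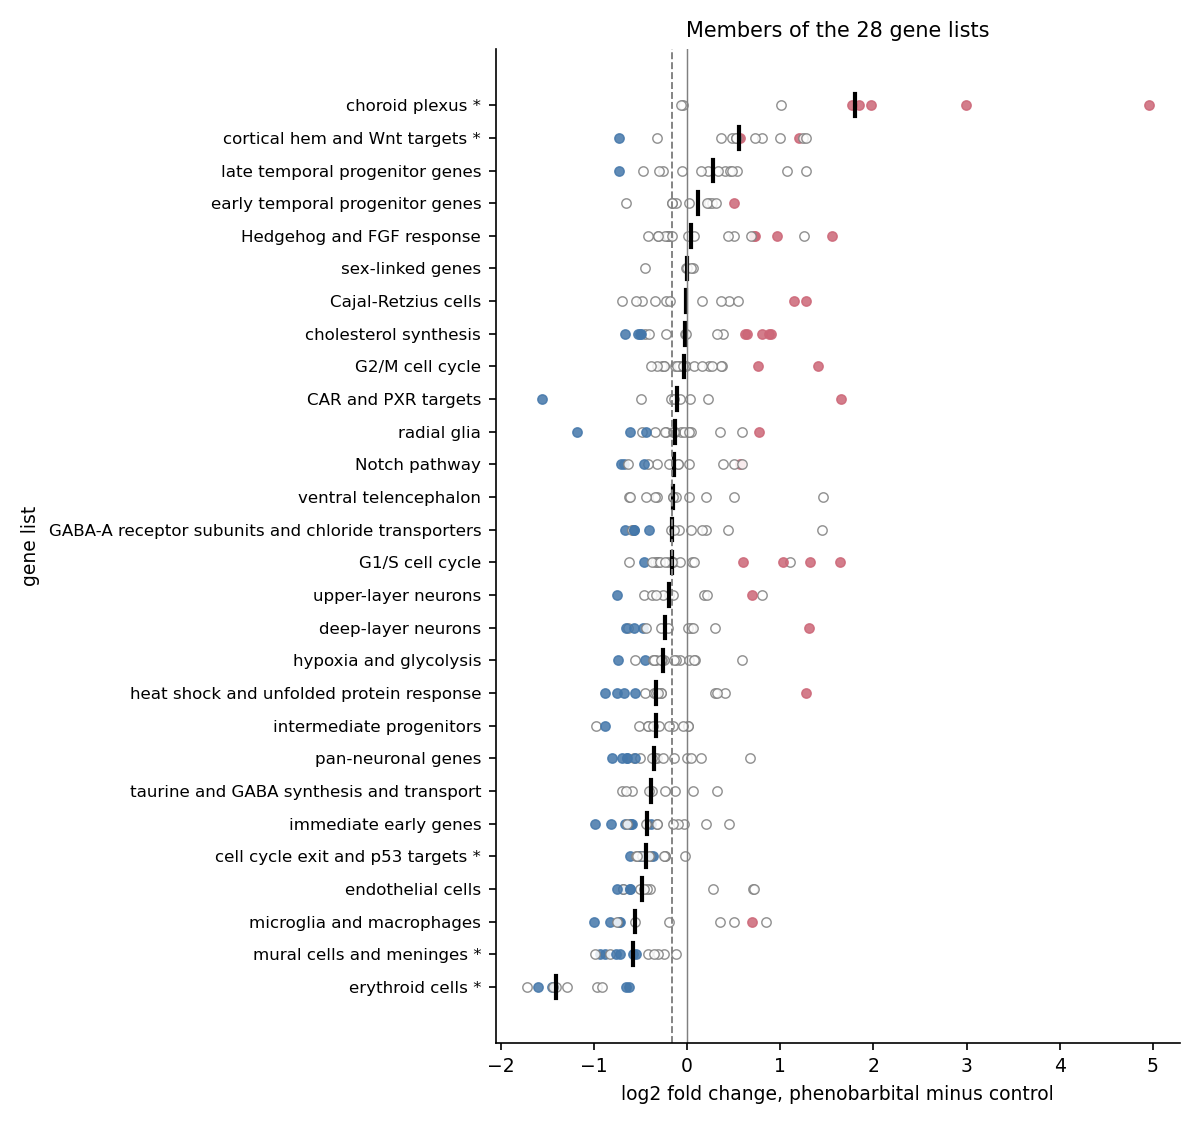
Log2 fold change, phenobarbital minus control (horizontal axis), of each tested member of 28 gene lists (vertical axis); filled points passed an adjusted p of 0.05, black bars are list medians, the dashed line is the median of all genes (-0.16), and asterisks mark lists past the camera test. The choroid plexus list lies highest, with a median of 1.80, and the erythroid list lowest, with -1.41.

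Of 11 genes of red blood cells tested, 5 fell, none rose and 6 did not pass, and adjusted over the list alone 7 fell. Epb42 and Slc4a1, proteins of the red cell membrane, fell by 1.45 ± 0.32 and 1.60 ± 0.40 on the log2 scale. Alas2, the first enzyme of erythroid heme synthesis, fell by 1.43 ± 0.29 (limma, adjusted p = 0.0279). The globin genes Hba-a1 and Hbb-y fell by 0.62 ± 0.10 and 0.66 ± 0.10. Hbb-y had -0.31 on its other probe, which did not pass. After quantile normalization Hba-a1 had -0.17 and did not pass, and Hbb-y turned to 0.14. Globin genes have near-identical copies, so their probes may read more than the named gene. The list's median lay 1.24 below that of all genes (camera adjusted p = 0.00766, and an adjusted p of 0.775 with an estimated correlation). As measured it was -1.41. It was -1.31 with the slide as a block, which rests on control replicate 1 alone, and -0.88 without control replicate 2.

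Of 13 genes of mural cells and meninges, all had a negative log2 fold change, 6 fell and 7 did not pass, and the counts adjusted over the list alone were the same. The matrix genes Lum, Col3a1 and Col1a2 fell by 0.93 ± 0.14, 0.88 ± 0.17 and 0.58 ± 0.12, and the meningeal factor Foxc1 by 0.76 ± 0.12 (limma, adjusted p = 0.0134). The list's median lay 0.42 below that of all genes (camera adjusted p = 0.0278, and an adjusted p of 0.687 with an estimated correlation). As measured it was -0.58, and with the slide as a block, which rests on control replicate 1 alone, it was -0.60. The call ended without control replicate 3 (camera adjusted p = 0.0664) and without phenobarbital replicate 2 (0.0936). Among 12 endothelial genes, 4 fell and 8 did not pass: Egfl7 fell by 0.75 ± 0.12, Flt1 by 0.69 ± 0.16, Sox17 by 0.62 ± 0.14 and Esam by 0.61 ± 0.15. Sox17 had -0.47 on its other probe, which did not pass. Adjusted over the list alone 5 fell and 1 rose. Of 11 microglia and macrophage genes, 4 fell and 6 did not pass, while the complement gene C1qb rose by 0.70 ± 0.12. Adjusted over the list alone 6 fell and 2 rose. Mrc1 fell by 0.997 ± 0.250, Aif1 by 0.83 ± 0.20 and Tyrobp by 0.72 ± 0.18. The endothelial and microglial lists did not pass the camera test (adjusted p = 0.363 and 0.831).

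The genes with the largest falls were of mixed kinds. Ifi202b, an interferon-inducible gene, fell by 2.19 ± 0.31 (limma, adjusted p = 0.0111) and by 2.37 on its other probe. The matrix genes Epyc and Hapln1 fell by 1.85 ± 0.19 and 1.84 ± 0.41, and the acyl-CoA thioesterase gene Acot3 by 1.94 ± 0.46. The kinase gene Tssk1 fell by 1.98 ± 0.45 and Epp13 by 1.91 ± 0.36. The pseudogene Cyp4b1-ps2 was lower as well, with a log2 fold change of -1.72 ± 0.20. Macc1 fell by 2.82 ± 0.57 and was above background on 1 of 3 phenobarbital arrays. The cytokine gene Tnfsf14 fell by 1.78 ± 0.44 and was above background on 2. Sgk2, Trim15 and Abi3bp were not well above background on any phenobarbital array and were at least 2.54-fold, 2.34-fold and 1.51-fold lower, and with normexp Sgk2, Trim15 and Abi3bp had log2 fold changes of -0.99, -0.90 and -0.83.

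Of 18 radial glia genes, 1 rose, 3 fell and 14 did not pass, with the same counts adjusted over the list alone. Emx2, a patterning factor highest in the medial and caudal cortex, rose by 0.78 ± 0.20 (limma, adjusted p = 0.0453). The adhesion gene Cdh2 fell by 0.61 ± 0.14, with -0.36 on its other probe, which did not pass. Vim fell by 0.44 ± 0.10, which turned to 0.0502 after quantile normalization. The tested probe of Notch1 fell by 1.18 ± 0.16, while its dimmer probe rose by 1.57, and the mean of both was 0.19. With every probe tested, dimmer probes of Ednrb and Prom1 rose by 1.52 and 1.22, while their brightest probes did not pass. Of 10 early temporal progenitor genes Dmrt3 alone passed, rising by 0.51 ± 0.12, and of 14 late ones Apoe alone, falling by 0.73 ± 0.11. Adjusted over the list alone none of the early genes passed, and Apoe did. A dimmer probe of Hopx, a late gene, rose by 1.23, while its brightest probe did not pass. Of 12 intermediate progenitor genes, Insm1 fell by 0.88 ± 0.12 (0.00878) and 11 did not pass. A dimmer probe of Eomes fell by 0.59, while its brightest probe did not pass. The pan-neuronal list had 5 falls, no rise and 12 members that did not pass (6 falls adjusted over the list alone). Among them the RNA-binding protein genes Elavl4 and Elavl3 fell by 0.70 ± 0.10 and 0.65 ± 0.14, and the microtubule genes Stmn2 and Dcx by 0.64 ± 0.12 and 0.56 ± 0.14. Elavl4 had -0.34 on its other probe and Dcx had -0.25 and -0.32 on its others, and none of these passed. Of 12 deep-layer genes, Lmo3 rose by 1.31 ± 0.16, Tbr1, Ldb2 and Foxp1 fell by 0.65 ± 0.14, 0.56 ± 0.11 and 0.47 ± 0.10, and 8 did not pass (1 rise and 4 falls adjusted over the list alone). Tbr1 had -0.34 on its other probe and Foxp1 had -0.21 and 0.13 on its others, and none of these passed. Of 11 upper-layer genes, Mef2c rose by 0.70 ± 0.16 (0.10 with normexp, which did not pass), Rorb fell by 0.76 ± 0.14 and 9 did not pass (1 rise and 2 falls adjusted over the list alone). None of 13 ventral telencephalon genes passed, and Sp8 had a log2 fold change of 0.20 ± 0.38. None of these lists passed the camera test, with adjusted p-values of 0.186 to 0.831.

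The GABA-A receptor, which phenobarbital acts on, and the taurine pathway were set out on their own. Of 14 genes for receptor subunits, their anchor and chloride transporters, 4 fell, none rose and 10 did not pass, with the same counts adjusted over the list alone. Gabrr1 fell by 0.40 ± 0.09 (limma, adjusted p = 0.0344). Slc12a2, the chloride importer NKCC1, fell by 0.57 ± 0.12 (0.0280). Slc12a5, the chloride exporter KCC2, had a log2 fold change of 1.45 ± 0.55 (0.114) and of -0.06 on its other probe. Values for subunits that did not pass were -0.59 ± 0.20 for Gabra3 (-1.29 on a dimmer probe that passed), -0.17 ± 0.12 for Gabrb2, and -0.14 ± 0.17 for Gabrg3. Those of Gabra2, Gabra4, Gabra5 and Gabrr2 were 0.05 ± 0.59, 0.44 ± 0.22, 0.20 ± 0.15 and 0.16 ± 0.32. With the slide as a block Gabrr1 and Slc12a2 did not pass. Both kept their sign, which was fixed in advance because their groups did not overlap. None of 10 genes of taurine and GABA synthesis and transport passed. Slc6a6, the taurine transporter, had a log2 fold change of 0.07 ± 0.10 (adjusted p = 0.677), and Csad, a taurine-synthesising enzyme, of -0.39 ± 0.17 (0.155). The camera test gave adjusted p-values of 0.767 for the receptor list and 0.680 for the taurine and GABA list. With fry, which does not compare a list with other genes, the receptor list passed downward (adjusted p = 0.0254) and the other did not (0.104). The receptor list's median as measured was -0.158, against -0.162 for all genes tested.

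Cell cycle genes were split. Of 20 G1/S genes, 4 rose, 1 fell and 15 did not pass. The cyclin gene Ccnd1 rose by 1.32 ± 0.14 (limma, adjusted p = 0.00501), the replication gene Gins2 by 1.64 ± 0.32, and the kinase genes Cdk2 and Cdk6 by 1.03 ± 0.22 and 0.60 ± 0.12, though Cdk6, a dim gene, had 0.08 with normexp and did not pass. Of 20 G2/M genes, Bub1b, a spindle checkpoint kinase, rose by 1.41 ± 0.13 (0.00345), Top2a by 0.76 ± 0.16, and 18 did not pass. Adjusted over the list alone these counts were the same for both lists. Each of these 6 genes rests on 1 tested probe. As measured, the G1/S list had a median of -0.16 and a mean of 0.11, and the G2/M list -0.04 and 0.08 (camera adjusted p = 0.611 and 0.186). The G2/M list passed in 3 of 21 alternatives (normexp, quantile normalization and the mean of a gene's probes). The list of cell cycle exit and p53 targets passed the camera test downward (adjusted p = 0.0456, and an adjusted p of 0.432 with an estimated correlation). It held 4 falls, no rise and 10 members that did not pass (7 falls adjusted over the list alone). Sesn2 fell by 0.62 ± 0.15, the pro-apoptotic Bbc3 by 0.52 ± 0.12, the cyclin-dependent kinase inhibitor gene Cdkn1c by 0.48 ± 0.12 and Mdm2 by 0.37 ± 0.09. The list's median lay 0.28 below that of all genes and was -0.44 as measured. This call passed in 9 of 21 alternatives. It was lost with the slide as a block, which rests on control replicate 1 alone (median as measured -0.35). Of 14 Notch pathway genes, Nrarp rose by 0.57 ± 0.11, Jag1, Heyl and Numbl fell by 0.68 ± 0.13, 0.71 ± 0.14 and 0.46 ± 0.11, and 10 did not pass (4 rises and 4 falls adjusted over the list alone).

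Of 17 immediate early genes, which respond to activity and handling, 7 fell, none rose and 10 did not pass (10 falls adjusted over the list alone). Egr2 fell by 0.98 ± 0.15 (limma, adjusted p = 0.0130), Egr1 by 0.61 ± 0.14, Ccn1 by 0.60 ± 0.11 and Maff by 0.59 ± 0.11. The immediate early list did not pass the camera test (adjusted p = 0.0593). It passed in 9 of 21 alternatives, among them quantile normalization and the slide as a block, which rests on control replicate 1 alone. Of 15 genes of heat shock and the unfolded protein response, 4 fell, 1 rose and 10 did not pass (7 falls and 2 rises adjusted over the list alone). Herpud1 fell by 0.88 ± 0.12, Trib3 by 0.76 ± 0.13 and Chac1 by 0.68 ± 0.11. Atf4 fell by 0.56 ± 0.10 on its brighter probe and rose by 1.49 on the other, with a mean of 0.47 that did not pass. Of 16 genes of hypoxia and glycolysis, Vegfa and Ndrg1 fell, by 0.45 ± 0.10 and 0.74 ± 0.17. Vegfa had -0.20 on its other probe, which did not pass. With every probe tested, 1 dimmer probe each of Ldha and Tpi1 rose, by 2.37 and 2.18, and 1 of Pfkp fell by 1.07. The brightest probes of Ldha, Tpi1 and Pfkp did not pass. Cholesterol synthesis genes went both ways, with 5 rises, 4 falls and 7 of 16 that did not pass (5 rises and 5 falls adjusted over the list alone). Lss rose by 0.88 ± 0.12, Fdft1 by 0.80 ± 0.11 and Dhcr7 by 0.63 ± 0.10. Fdft1 had 0.61 on its other probe, which did not pass. Of 8 tested targets and members of the CAR and PXR system, through which phenobarbital induces drug metabolism in liver, the glutathione transferase gene Gstm3 rose by 1.65 ± 0.29 and the receptor gene Nr1i3 fell by 1.55 ± 0.24. Gstm3 was above background on 1 of 3 control arrays, and had 0.42 with normexp and did not pass. A dimmer probe of Gstm1 rose by 1.04, while its brightest probe did not pass. None of 5 sex-linked genes passed, with -0.00 ± 0.21 for Eif2s3y and -0.01 ± 0.21 for Ddx3y. For the lists of the Notch pathway, stress responses, hypoxia, cholesterol, CAR and PXR, and sex-linked genes, camera gave adjusted p-values of 0.221 to 0.831, and the cholesterol list passed with normexp alone.

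Different probes of a gene often disagreed. Among genes with several tested probes, 189 rose on the brightest, and 77 of these rose on another probe as well. Of 428 that fell, 102 fell on another probe and 36 rose on another. Over 3164 pairs of probes for 1 transcript accession, the log2 fold changes of the brighter and dimmer probe correlated with Pearson's r = 0.28 across pairs, which are not independent replicates. In 221 pairs 1 probe rose by over 1.2 and the other did not, and in 20 both did.

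**Figure D3:**
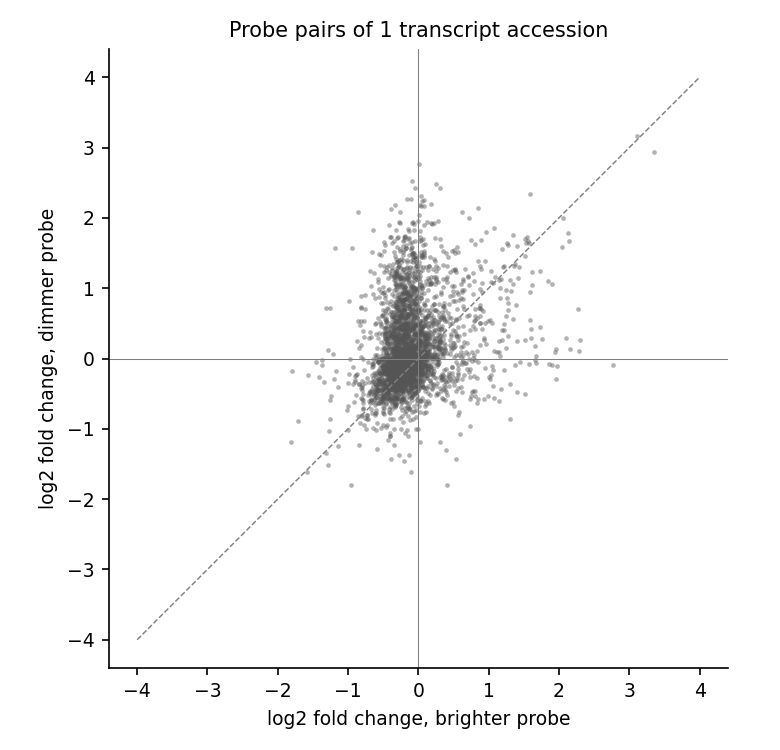
Log2 fold change, phenobarbital minus control, of the brighter (horizontal axis) and dimmer probe (vertical axis) in 3164 pairs of probes for 1 transcript accession; each point is a pair and the dashed line marks equal values. Many pairs lie above 0 on the vertical axis and near 0 on the horizontal one, and r is 0.28.

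Of the 28 lists, 5 passed the camera test, and none passed with an estimated correlation, the lowest adjusted p being 0.295. The list count is no larger than that of other divisions of the arrays: 6 of the 10 splits of the 6 arrays into 3 and 3, the real one included, gave 5 or more lists. Bright genes lay lower than dim ones, with a median log2 fold change of -0.39 over 1058 genes with a mean signal over 6 and of -0.07 over 4270 genes under -4. Most of the 103 named genes that passed did not pass with the slide as a block, which rests on 1 control array. All 103 kept their sign, which was fixed in advance for genes whose groups did not overlap.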

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

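The slide as a random block and both settings on a gene's probes (their mean, and genes whose probes lay within 1 of each other) were chosen after the data were seen. Of 103 named genes that passed, 99 kept their sign and 6 their call (Calml4, Lpin1, Sp5, Bub1b, Epyc and Cyp4b1-ps2) under every alternative run. The others were Vim (0.0502) and Hbb-y (0.14) after quantile normalization, and Notch1 (0.19) and Atf4 (0.47) with the mean of a gene's probes; for the last pair the probes' opposite changes account for it, and for the first pair the cause was not tested. The choroid plexus, hem and erythroid lists passed camera in all 21 alternatives with a preset correlation, mural cells and meninges in 19, and p53 targets in 9, with the highest adjusted p 0.00207, 0.00153, 0.0433, 0.0936 and 0.228. With the correlation estimated, 0 lists passed, and with fry 9.

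Against 4234 genes changed, 1580 higher, 2654 lower and 1158 changed at least 2-fold, counts moved by over 1.5 times as follows, and the cause was not tested unless stated. With normexp 4735 were lower and 767 changed at least 2-fold. Quantile normalization gave 1385 lower. The percentile over probes above background on all arrays gave 2716 changed and 1104 lower, and the median 2470 and 1028. Without a filter on dim probes, where more names share the adjustment, 1486 changed, 896 higher and 590 lower. Testing every probe gave 2415 higher, over more tests. Array weights gave 9364 changed, 2699 higher and 6665 lower. The slide as a block, with 2 residual degrees of freedom, gave 771 changed, 608 higher, 163 lower and 726 at least 2-fold.

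With the replicate number as a block (replicate block), 295 changed, 270 higher, 25 lower and 295 at least 2-fold. The deviations of same-numbered arrays correlated at 0.08, -0.16 and -0.35, which shows no pairing, though 3 values cannot exclude one. Leaving out each replicate gave 881 to 4406 changed, 644 to 1867 higher, 211 to 2539 lower, 669 to 1244 at least 2-fold and 3 to 6 lists, with 1 array fewer in each fit. Signal over background limits the genes below it in 1 group to bounds.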

Other observations

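Tests chosen after the result was seen were those of the slide and of the whole mRNA for the risen probes, the slide for the choroid plexus genes, the arrays left out, and the count of cells other than neural cells. The 3 gene lists tested here were written after other values had been seen, and before those of their own genes.

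Motile cilia genes, not described above, moved both ways. Of 15 tested, 5 rose, 2 fell and 8 did not pass, with the same counts adjusted over the list alone. Foxj1, the master regulator of motile cilia, rose by 1.21 ± 0.24 (limma, adjusted p = 0.0263), Rsph1 by 1.37 ± 0.30, Ccno by 1.14 ± 0.21, Cfap126 by 1.06 ± 0.24 and Hydin by 0.62 ± 0.16. Rsph4a fell by 1.25 ± 0.29, while its other probe had 0.71, and Mcidas fell by 0.73 ± 0.19. The cilia list's median lay 0.25 above that of all genes (camera adjusted p = 0.0132, and an adjusted p of 0.370 with an estimated correlation).

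In the choroid plexus list 5 of 8 genes rose. The slide stays open: within slide 1 the list's median difference was 2.23, but that slide holds a single control array and control values spread widely (SD 2.17 for Ttr). Tissue of the diencephalon and eye, in an amount that would lift its genes as much as the choroid plexus list, is argued against. The 13 of them tested had a median of -0.41 with an upper quartile at 0, 2 fell (Irx3 and Mitf, also after adjustment over the list alone) and none rose (camera adjusted p = 0.494). A smaller amount stays open, as most were above background on every control array and 5 of 18 were not tested. Vax1 and Rax, above background on 1 of 3 control arrays, had 1.41 ± 0.59 and 0.76 ± 0.52 and did not pass. Pmel and Irx5, also dim, had -0.59 ± 0.30 and -0.14 ± 0.41. More choroid plexus cells in the cultures is a candidate explanation that stays open: a second list of 18 tested choroid plexus genes had a median of -0.0634 and a mean of 0.14 (camera adjusted p = 0.153, and an adjusted p of 0.370 with an estimated correlation), with Lbp and Car12 past the threshold (Lbp alone when adjusted over the list alone). In all, 7 of the 18 had a positive log2 fold change. The brightest members in the phenobarbital arrays were Igfbp2, which other tissue also expresses (-0.09 ± 0.16), Spint2 (1.71 ± 0.50) and Krt18 (0.85 ± 0.31). In the control arrays they were Igfbp2, Slc31a1 (-0.32 ± 0.12) and Steap1 (-0.05 ± 0.16). None of these passed. Choosing by brightness in 1 group favours genes high in that group, so neither choice decides the question. Whether the dissections held more medial tissue or the exposure changed it was not tested.

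Probes that rose by over 1.2 numbered 937, against 280 that fell as far. The slide stays open: within slide 1 their median difference was 1.47, but it rests on a single control array, and the probes were chosen on these same arrays. For the 327 of them with another tested probe of the same accession, a change of the whole mRNA is argued against for most, since the other probes had a median of 0.0726 (quartiles -0.16 and 0.55), and with probes chosen on 2 arrays per group and measured on the arrays left out, the 9 choices gave medians of 1.12 to 1.83 for the chosen probes and -0.12 to 0.13 for the others (upper quartiles 0.39 to 0.72); for the 20 pairs in which both rose it stays open. A candidate explanation is less complete labelled product in the controls, as labelling starts at the 3' end and a farther probe is dimmer: the risen probe was the dimmer in 80.5% of 221 pairs (exact 95% interval 74.7 to 85.5), against 6 of 19 pairs with 1 fallen probe. Brightness stands in for probe position, which was not analysed here, and isoform use stays open as well. Over all genes, the median log2 fold change was -0.07 at a mean signal under -4 and -0.39 over 6. This trend with brightness was not separated from the share of dimmer risen probes, so the share is not specific to labelling.

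The erythroid list held 5 falls among 11 genes and the mural and meningeal list 6 among 13. Array brightness is argued against as the whole cause, since against the 200 genes nearest in signal the members' median was -0.65 (upper quartile -0.26). The slide stays open: the median within slide 1 was -0.76, a value set in advance as arguing against it, but a bound on a slide with a single control array cannot do so. Fewer cells other than neural cells with phenobarbital is a candidate explanation that stays open. The medians of the erythroid, mural, endothelial and microglial lists lay at least 0.32 below that of all genes (-0.32 the nearest, -1.24 the farthest). The erythroid and mural lists are the pattern itself, so their falls cannot speak for its cause. The endothelial and microglial medians lay 0.32 and 0.40 below that of all genes, and their means as measured were -0.29 and -0.22. The endothelial and microglial lists did not pass camera and C1qb rose, so a loss common to all of these cells was not shown.

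With 10 splits of the 6 arrays into 3 and 3, no share under 0.05 is possible. The real split gave 4234 genes changed, 1580 higher, 2654 lower and 1158 changed at least 2-fold, and 1 split, the real one, reached each count. The highest of the other splits gave 1 gene changed and 1 at least 2-fold, and 1 in a single direction, which is arbitrary for such a split and was set against both real directions. For lists the real split gave 5 and the highest other 9, from control replicates 1 and 3 with phenobarbital replicate 1 against the rest, and 6 splits gave 5 or more.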
